A study of Drosophila melanogaster with 2 samples.

How the data were processed

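The samples were whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying, per the labels. The flies carried a transgene that makes CG4360 as a fusion with enhanced green fluorescent protein (eGFP). Chromatin was sheared by sonication to fragments of 200 to 800 bp, and an antibody against GFP was used for the immunoprecipitation, per the labels. There was 1 group with 2 biological replicates. The labels point to a control experiment, which was not analysed here.

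The deposited files were lists of peaks on the dm6 assembly, per the file headers and labels. Each replicate had its own pair of lists, and 2 further pairs were made from the alignments of both replicates. Within a pair, one list held ranked calls and the other held the calls that passed a threshold on the irreproducible discovery rate (IDR), which measures how well the rank of a call repeats between data sets. The list made from the pair of true replicates is called conservative, as the authors named it, and the other list from both replicates is called pooled. The aligner, the peak caller and their versions are not given in the sources used here.

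The authors deposited for each peak a signal value, whose scale is not given in the sources used here. It was used to describe, rank and compare peaks within 1 list. It was also set beside the replicate values held in the conservative ranked list. The deposited lists also held a score of at least 830 for every thresholded peak, and the deposited ranked lists gave −log10 of the global IDR, with a value of at least 2 for every thresholded peak. The deposited threshold was therefore an IDR of at most 0.01. The conservative ranked list also gave the signal value of the matching peak in each replicate. Which of these columns belonged to which replicate was not stated, so they are called first and second. The number of reads behind each list is unknown, so no interval or detection limit that needs read depth is given. Intervals on shares are exact binomial 95% intervals. Intervals and p-values cover counting error only.

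Peaks were compared with the Ensembl release 115 annotation of the release 6 assembly, whose chromosome lengths held every peak of the major arms. Analyses of position and sequence used the conservative peaks on arms 2L, 2R, 3L, 3R, 4, X and Y. Each peak was counted as deposited. Among the 5697 conservative peaks, 17 repeated the coordinates of another. Some neighbouring summits carried the same pair of replicate signal values, so neighbouring conservative peaks can match the same replicate peak. Such peaks are not separate sites, but the counts and tests treat them as separate. A summit within 500 bp of any annotated transcript start was called promoter. Other summits were assigned, in order of priority, to 5′ UTR, 3′ UTR, coding sequence, intron, other exon or intergenic. The background was the set of 120768 relaxed calls, which are ranked calls of the same list that did not pass the threshold. Differences were tested with 2-sided Fisher exact tests and adjusted by the Benjamini-Hochberg method within each family at 0.05. Odds ratios carry a 95% interval on the log scale, with 0.5 added to each cell where one was 0.

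For 19 gene lists, members with a summit within 500 bp of a transcript start were compared with all other protein-coding genes. Any annotated start of a gene counted, so genes with many starts had more chances, and the tests did not adjust for this. For 6 gene types the comparison was with all other genes. Symbols were matched exactly, and members absent from the annotation under their symbol were left out. For sequence, windows reaching 50 bp to each side of the summit were compared with windows centred 500 bp to either side. A total of 26 motifs and all 8192 distinct 7-base words, each counted together with its reverse complement, were tested. Lists, motifs, tests and most alternatives were fixed before the data were examined.

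Replicate lists were compared with bedtools 2.31.1 at a reciprocal overlap of at least 0.5, and the chance level came from 100 shuffles of the replicate 2 peaks within their chromosomes. Signal values were compared with 2-sided permutation tests with 100000 resamples. The smallest p these can give is 1e-05. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and pysam 0.24.0, and plots used matplotlib 3.10.9.

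The items named in the text followed a rule. They were CG4360, the 15 conservative peaks with the highest signal value, up to 4 members per gene list in order of signal, and the 5 words with the lowest p that were more frequent at summits and did not match a better one over an end-to-end overlap of 5 or more bases. All motifs past the threshold were counted and named. Members and regions named outside the rule are marked where they appear. Outside the gene lists, the gene named for a peak is the protein-coding gene with the nearest transcript start. A list member needed only a summit within 500 bp of any of its starts, so another gene's start could lie nearer. The same peak could therefore count for members of different lists, as for Dref (63 bp away) and RpL13 (21 bp away). Neither way of naming shows that a peak acts on the gene.

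The procedures were tested on simulated data. A promoter odds ratio of 3 planted in the relaxed calls was recovered with a mean of 3.12 over 50 draws, and 1 of 50 draws with nothing planted gave a call. Gene lists of the real sizes with a planted odds ratio of 5 were called in 72.0% of cases, against 1.56% of lists with nothing planted. Planted lists of 15 or more members were called in 92% of cases, so shorter lists were called less often than 72.0%. A short list that did not pass can therefore still differ. All 20 words planted in 2% of windows were recovered, and 0 of 8192 words were called with nothing planted. Of 4000 simulated peaks with 60% shared, 60.1% were found as shared. These peaks all had the same width and shift, so the overlap rule was not tested on peaks of unequal width.

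Alternatives covered each replicate list alone, the pooled list, other distances to a transcript start, gene 5′ ends only, random positions as background, all sequences, wider windows, another background distance, relaxed calls matched on GC content, and other definitions of shared peaks. An IDR of at most 0.01 had been planned as a stricter threshold and turned out to be the deposited one. An IDR of at most 0.001 was therefore added after seeing the data. Leaving out peaks with a signal value under 30, adding calls past the threshold that the thresholded list lacks, and matching 3 renamed gene symbols were also chosen after seeing the data.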

Results

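The data were peaks of an anti-GFP chromatin immunoprecipitation from whole fly embryos that carried an eGFP-tagged form of CG4360. CG4360 is a gene of the zinc finger transcription factor type on arm 3R. Replicate 1 gave 4519 peaks out of 90253 ranked calls, and replicate 2 gave 3682 out of 88251. Both replicates together gave 6198 peaks in the pooled list and 5697 in the conservative list. Median peak widths were 380 bp and 336 bp in the replicates and 390 bp in both lists made from the pair. Conservative peaks covered 1976 kb in all.

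The first question was how well the replicates repeated each other. Of 4519 replicate 1 peaks, 2455 had a replicate 2 peak at a reciprocal overlap of at least 0.5, which is 54.3% (95% interval 52.9 to 55.8). In the other direction 2446 of 3678 peaks on the major arms were shared, which is 66.5% (65.0 to 68.0). Shuffled replicate 2 peaks met 0.728% ± 0.127 (SD, 100 shuffles) of replicate 1 peaks, and no shuffle exceeded 0.996%. Replicate 1 had 1.23 times as many peaks as replicate 2, so the shares are bounded by the list lengths. Of the 5692 conservative peaks on the major arms, 2314 matched a peak in both replicate lists, 1237 matched replicate 1 alone, 585 matched replicate 2 alone and 1556 matched neither. These matches were to thresholded peaks at the same reciprocal overlap. Every conservative peak also had a matching call with a signal value in each replicate.

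Peaks found in both replicates were stronger. Median signal in replicate 1 was 91.0 for shared and 51.5 for unshared peaks, a ratio of 1.77 (2-sided permutation p = 1e-05, the smallest possible). In replicate 2 the medians were 77.3 and 53.6, a ratio of 1.44 (permutation p = 1e-05). Across conservative peaks, the signal values of the matching peaks in the replicates had a Spearman correlation of 0.768 and a Pearson correlation of 0.876 on the log2 scale. These peaks had been selected by IDR for similar ranks in the same replicates, so high values were largely set by the selection. Over all 126636 ranked calls on the major arms the values were lower, at 0.365 and 0.476.

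**Figure D1:**
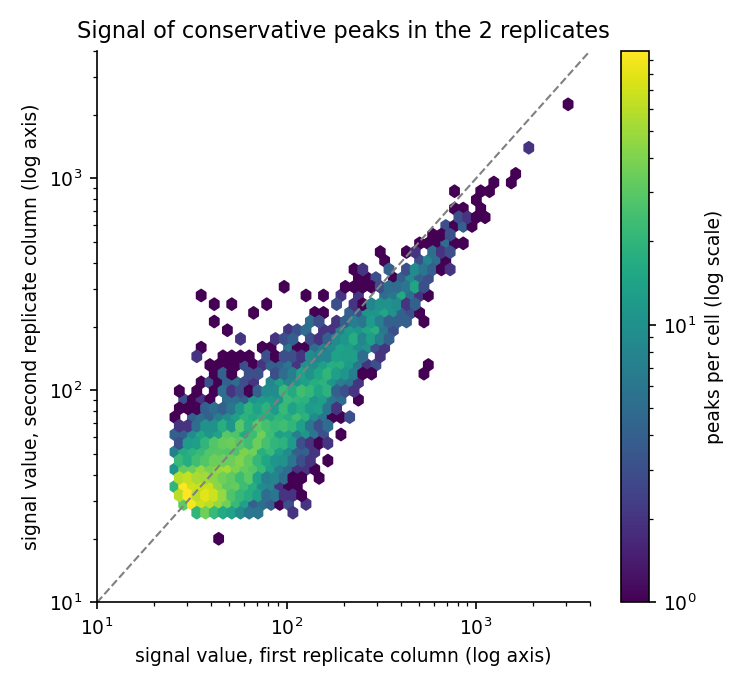
Signal value of the 5692 conservative peaks in the first (x axis) and second (y axis) replicate column, on log axes, with colour giving the number of peaks per cell and the dashed line marking equal values. Peaks spread along the line, with a Spearman correlation of 0.768, and the first column was higher for 64.7% of them.

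The strongest sites lay near genes of varied function. The peak with the highest signal, 5302, lay on 2R from 14000618 to 14001177 in intronic sequence within mam, which encodes the Notch co-activator Mastermind. The next lay at the promoter of AGO2, the Argonaute of the small interfering RNA pathway (3L, 15554059 to 15554705, signal 3402). The third was an intronic peak assigned to grh, the epidermal transcription factor Grainyhead (2R, 17822020 to 17822730, signal 3361). The promoters of bab2, a BTB transcription factor (2644), and ced-6, an engulfment adaptor (2567), followed. Of the 15 strongest peaks, 2 intronic ones were assigned to tou, a chromatin factor, with signals of 2247 and 1832.

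Promoter peaks were also present near Cbl, an E3 ubiquitin ligase of receptor signalling (2106), toy, a Pax6 gene on chromosome 4 (1750), and Ugalt, a nucleotide sugar transporter (1643). The peak nearest to scyl (1745) lay 5813 bp from a transcript start of that gene and at a start of another transcript. An intronic peak was assigned to kibra, a Hippo pathway gene, at a distance of 9846 bp (1707). Peaks in coding sequence were assigned to pico (1882), to the LIM-only gene Bx (1570) and to CG6912 (1523). Of these 15 peaks, 13 had the word CAACAAC within 50 bp of the summit, and those at toy and Ugalt did not.

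At the CG4360 gene itself (FBgn0038787, 3R, 20324274 to 20328003, minus strand) the lists differed. The conservative list and the replicate 1 list each had 0 peaks in the gene or within 2000 bp of it. Replicate 2 had 2 peaks, with summits 414 bp and 166 bp from the gene's 5′ end and signals of 31.5 and 25.7, at ranks 3444 and 3472 of 3678. The pooled list also had 2 peaks, with summits 92 bp and 108 bp from that end and signals of 20.4 and 56.3. The conservative ranked list held 10 relaxed calls there, with signals of up to 56.3.

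A CAA repeat was more frequent under the summits than beside them. CAACAAC or its reverse complement GTTGTTG was present within 50 bp of 2569 of 5692 summits (45.1%), against 549 of 11384 flanking windows (4.82%), an odds ratio of 16.2 (95% interval 14.7 to 17.9). CAGCAAC was present at 18.5% of summits and 3.42% of flanks (odds ratio 6.41, adjusted Fisher p = 2.84e-225), and CAACAGC at 16.1% of summits and 341 of 11384 flanks (6.20, adjusted p = 3.82e-192). CAACAAA, at 18.8% and 5.80% (3.77, adjusted Fisher p = 9.40e-143), and CAGCAGC, at 13.3% and 4.15% (3.54, adjusted p = 5.94e-95), completed the 5 named words. All 5 were repeats of CAA or CAG units or close variants. Against relaxed calls matched on GC content, CAACAAC had an odds ratio of 18.1 and CAGCAGC 3.22.

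In all, 530 of 8192 words were more frequent and 1025 less frequent at summits, by Fisher exact tests with adjusted p under 0.05. Words sharing bases are not independent, and the mean GC content was 43.9% at summits and 41.1% in flanks. The number of more frequent words was 332 in replicate 2 alone and 991 with windows of 100 bp to each side.

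The CAA repeat rose with the strength of the peak, in a breakdown chosen after the data were examined. CAACAAC was present at 13.7% (95% interval 11.0 to 16.8) of summits in the decile of peaks with the lowest signal. The word was present at 46.4% (42.2 to 50.6) in decile 6 and at 87.7% (84.7 to 90.3) in the highest decile. Flanking windows held it at 2.99% to 6.15% across the deciles. Peaks with the word had a median signal of 154.9, against 82.9 for those without it, a ratio of 1.87 (permutation p = 1e-05).

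**Figure D2:**
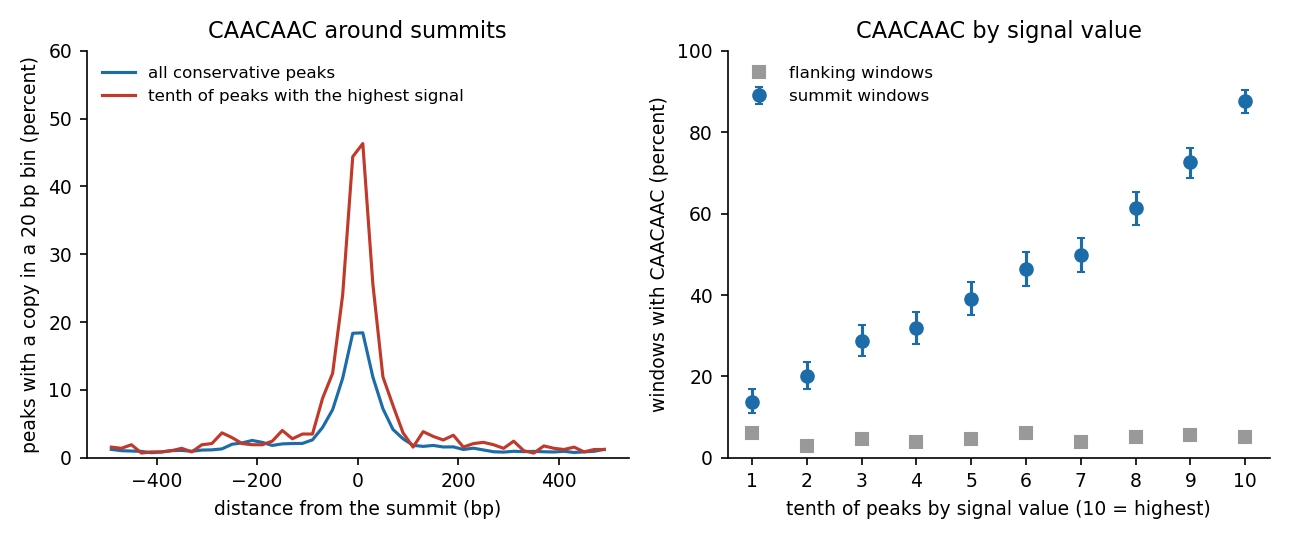
Left, percent of conservative peaks with a copy of CAACAAC, on either strand, starting in each 20 bp bin around the summit (x axis, bp), for all 5692 peaks and for the 570 in the highest decile by signal. Right, percent of summit windows (circles, with exact 95% binomial intervals) and flanking windows (squares) with the word, per decile of peaks by signal value; summit windows run from 13.7% to 87.7%.

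Of the 26 motifs tested, 4 were more frequent at summits than in flanks and 12 were less frequent. The higher ones were CTCF (0.843% against 0.325%, odds ratio 2.61, adjusted Fisher p = 3.96e-05) and the GAGA repeat (4.90% against 2.61%, 1.92, adjusted p = 3.44e-13). The CA repeat (5.11% against 3.42%, 1.52, adjusted Fisher p = 6.79e-07) and the E-box CAGCTG (5.66% against 4.32%, 1.33, adjusted p = 0.000324) were the others. Motifs of several patterning and core promoter factors were scarcer at summits. Bicoid had an odds ratio of 0.518 (adjusted Fisher p = 1.19e-09), Tramtrack 0.527, STAT 0.583, the TATA box 0.639, Caudal 0.668, AP-1 0.669 and the homeodomain core 0.671.

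The E-box CATATG (0.723), the Su(H) site (0.726), the Hunchback site (0.737), the initiator (0.769) and the A tract (0.861) were also lower. Zelda, DRE, BEAF-32, motif 1, Ohler motif 6, E-box CACGTG, Grainyhead, GATA, Su(Hw) and Pho sites did not pass the threshold. Against relaxed calls matched on GC content, the GAGA repeat had an odds ratio of 3.86, CTCF 3.72 and the CA repeat 1.91. The E-box CAGCTG lost its call there (odds ratio 1.05, adjusted Fisher p = 0.669), and so did CATATG, the TATA box, AP-1, STAT, Hunchback and the A tract. DRE (2.42) and motif 1 (2.26) passed there, while in replicate 2 alone they stood at 1.03 and 0.864, and among peaks over 500 bp from a start at 0.182 and 0.909, without passing.

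Peaks gathered at transcript starts. Promoters held 2353 of 5692 summits (41.3%), against 16.3% of the relaxed calls, an odds ratio of 3.62 (95% interval 3.43 to 3.82). Among 5′ UTRs beyond 500 bp of a start the shares were 2.79% and 0.995% (odds ratio 2.86, adjusted Fisher p = 3.25e-27). Coding sequence held 5.62% of summits against 20.2% of relaxed calls (0.235, adjusted Fisher p = 6.19e-208). The 3′ UTRs held 1.48% against 4.38% (0.327), intergenic sequence 13.9% against 20.7% (0.615) and introns 34.1% against 36.8% (0.890, adjusted Fisher p = 4.90e-05). Other exons did not differ past the threshold (0.808% against 0.608%, adjusted Fisher p = 0.0681). They passed in replicate 1 alone (1.47, adjusted Fisher p = 0.0248), with a distance of 250 bp (1.47, adjusted p = 0.00281), with gene 5′ ends only (1.38, adjusted p = 0.0329) and against random positions (1.48, adjusted p = 0.0161). The call for introns was lost in replicate 2 alone (0.943) and with a distance of 250 bp (0.989), and turned with gene 5′ ends only (1.06). The median distance of a summit to a transcript start was 807 bp, against 2417 bp for relaxed calls.

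**Figure D3:**
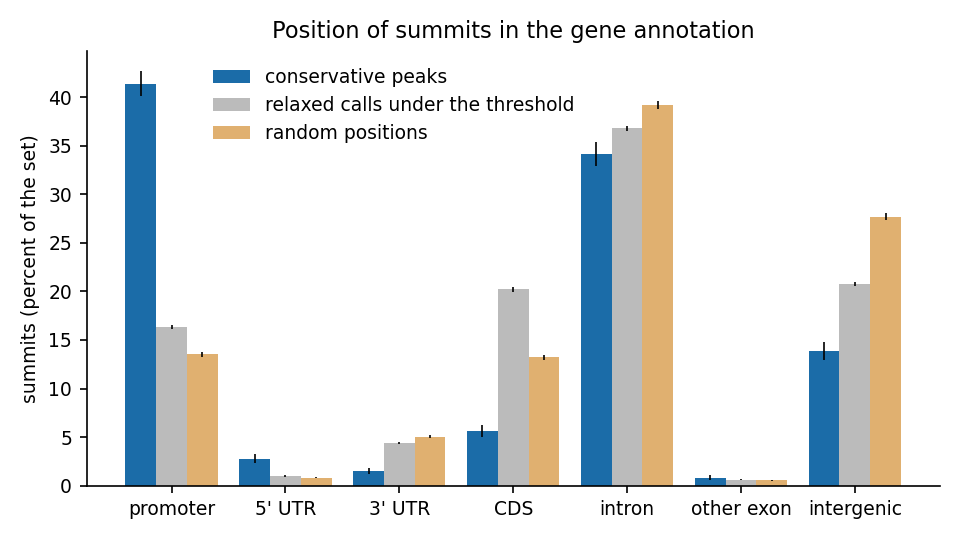
Percent of summits (y axis) in each annotation category (x axis) for the 5692 conservative peaks, the relaxed calls under the threshold and random positions on the same arms, with exact 95% binomial intervals. Promoters hold 41.3% of the peaks and 16.3% of the relaxed calls.

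Peak density ran from 38.8 to 45.6 per Mb on the 5 large arms and was lower on chromosome 4 and the Y. Arm 3L carried 45.6 peaks per Mb (odds ratio against relaxed calls 1.16, adjusted Fisher p = 3.72e-05), 2R carried 44.2 (1.12, adjusted p = 0.00246), 2L 41.3 (0.994, adjusted p = 0.886) and 3R 38.8 (0.880, adjusted p = 0.000193). The X carried 45.2 per Mb (0.907, adjusted Fisher p = 0.00663), chromosome 4 carried 12 peaks (8.90 per Mb, 0.644, adjusted p = 0.175) and the Y carried 0 peaks against 227 relaxed calls (adjusted p = 0.000193). The result for the X turned in the replicate lists alone, with an odds ratio of 1.07 in replicate 1 (adjusted Fisher p = 0.221) and 1.12 in replicate 2 (adjusted p = 0.0198). Against random positions it also passed in the opposite direction (1.10, adjusted Fisher p = 0.00982). Chromosome 4 passed in replicate 2 alone (0.345, adjusted Fisher p = 0.00248), in the pooled list (0.571, adjusted p = 0.0411) and against random positions (0.221, adjusted p = 1.61e-10), and stood at 0.973 in replicate 1 alone. Arm 2R and the Y lost their calls in each replicate list, 3R lost its call once the calls absent from the thresholded list were added (0.952, adjusted p = 0.144), and 3L in replicate 2 alone (adjusted Fisher p = 0.0528).

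The gene lists addressed which kinds of genes had a peak at a transcript start. Of 13968 protein-coding genes, 2214 had a summit within 500 bp of a start (15.9%). By Fisher exact tests adjusted over the 19 lists, 7 lists were above that level and 1 was below it. Whether these starts carry signal in flies without the tagged protein is open, because the control experiment was not analysed. The list with the most members that had such a summit was the cytosolic ribosomal proteins, with 51 of 92 (55.4%, odds ratio 6.74, 95% interval 4.45 to 10.2, adjusted Fisher p = 5.05e-17). Its 4 strongest members were RpL34b (signal 235.5), RpS3 (216.7), RpL7 (173.8) and RpL19 (167.9). Promoter peaks of this list had a median signal of 85.1, against 103.9 over all conservative peaks. The odds ratio was 3.55 in replicate 2 alone and 3.37 in replicate 1 alone, and at an IDR of at most 0.001, a threshold chosen after seeing the data, the share fell to 18.5% (odds ratio 2.19, adjusted Fisher p = 0.0202).

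Lists of signalling and hormone genes were also above the level where any annotated start of a gene counted. None of the lists in this paragraph passed with gene 5′ ends only, as given below. JAK/STAT, EGFR, JNK and Hippo signalling had 9 of 16 members (odds ratio 6.85, adjusted Fisher p = 0.00155). They included spi, an EGFR ligand (signal 1003), ex, a Hippo pathway gene (781.6), the ETS factor pnt (678.6) and Egfr, the receptor (355.2). The ecdysone response had 7 of 11 (9.32, adjusted Fisher p = 0.00216), with the nuclear receptor genes Eip75B (232.4), Hr3 (208.5), EcR, the hormone's receptor (102.9), and Eip78C (100.3). Notch and Enhancer of split genes had 7 of 16 (4.14, adjusted Fisher p = 0.0180), with E(spl)m8-HLH (590.9), Su(H), the pathway's DNA-binding factor (409.0), numb (125.8) and E(spl)m5-HLH (97.0). The Notch list lost its call with a distance of 250 bp (2.42), at an IDR of at most 0.001 (2.21), without signal under 30 (3.21) and among genes with a relaxed call (3.40). It did not pass in replicate 2 alone (1.95, adjusted Fisher p = 0.316), and the ecdysone list missed the threshold there (4.83, adjusted p = 0.0534) and had an odds ratio of 5.48 in replicate 1 alone. With a distance of 1000 bp the odds ratios were 18.2 for the ecdysone list and 6.74 for the Notch list.

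Genes of chromatin and of epithelia formed the remaining lists above the level. Polycomb and trithorax group genes had 7 of 13 (6.21, adjusted Fisher p = 0.00558), with ph-p (620.3), Psc (337.0), brm (261.4) and Su(z)2 (158.2). Insulator and architectural protein genes had 6 of 11 (6.39, adjusted Fisher p = 0.00959), with M1BP (519.5), pita (235.0), Trl, which encodes GAGA factor (205.6), and Cp190 (154.4). Trachea and epidermis genes had 7 of 12 (7.45, adjusted Fisher p = 0.00358), with sna (1107), grh (845.8), vvl (460.0) and trh (380.9). The insulator list lost its call with a distance of 250 bp (4.15, adjusted Fisher p = 0.0955). With gene 5′ ends in place of all transcript starts, 4 lists passed, and the ecdysone (1.42, adjusted Fisher p = 0.826), signalling (2.13, adjusted p = 0.546), insulator (2.40, adjusted p = 0.422) and Notch (3.85, adjusted p = 0.0550) lists did not.

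Lists of patterning genes had peaks at some members and did not pass in the conservative list. Gap, pair-rule and segment polarity genes had 6 of 20 (2.28, adjusted Fisher p = 0.190), including run (1197), ptc (270.8), hb (148.1) and odd (143.8). Hox genes had 3 of 8 (3.19, adjusted Fisher p = 0.190), namely Abd-B (457.6), abd-A (122.9) and Dfd (65.7). Dorsoventral and mesoderm genes had 4 of 14 (2.13, adjusted Fisher p = 0.328), namely sna (1107), tin (175.7), dpp (119.8) and rho (85.8). Proneural and neuroblast genes had 6 of 17 (2.90, adjusted Fisher p = 0.0855), including brat (964.8), grh (845.8), pros (483.4) and insc (272.4). In the pooled list 10 gene lists passed, among them the segmentation list (3.25, adjusted Fisher p = 0.0272) and the proneural list (3.41, adjusted p = 0.0315). The proneural list also passed in replicate 2 alone (adjusted Fisher p = 0.0168) and in replicate 1 alone (adjusted p = 0.0379).

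Cell cycle and replication genes had 4 of 17 (1.63, adjusted Fisher p = 0.393), among them the cyclins CycA (1202) and CycE (944.9), and also Dp (158.8) and E2f1 (157.1). Heat shock genes had 4 of 10 (3.54, adjusted Fisher p = 0.113), namely Hsp27 (279.7), Hsp83 (171.4), Hsp26 (105.4) and Hsp22 (82.7). With a distance of 1000 bp this list passed (6.06, adjusted Fisher p = 0.0142). Neuron differentiation had 2 of 12 (1.06, adjusted Fisher p = 1), namely elav (244.2) and para (235.0), muscle structural genes had sls alone of 13 (108.3, adjusted p = 0.789), and germ line and pole cell genes had pum alone of 10 (130.0, adjusted p = 1).

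Proteasome subunits had 2 of 32 (0.353, adjusted Fisher p = 0.299), namely Rpn2 (204.7) and Rpn3 (74.7). Oxidative phosphorylation genes had 8 of 80 (0.588, adjusted Fisher p = 0.247), with ND-ASHI (734.8), ND-B22 (667.2), ND-B18 (460.1) and COX7C (137.1) the strongest. The replication-dependent histones had 0 of 111 (adjusted Fisher p = 8.42e-08). Only 3 of these 111 repeated genes had any relaxed call at a start, and among genes with a relaxed call the list no longer passed (adjusted Fisher p = 1).

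**Figure D4:**
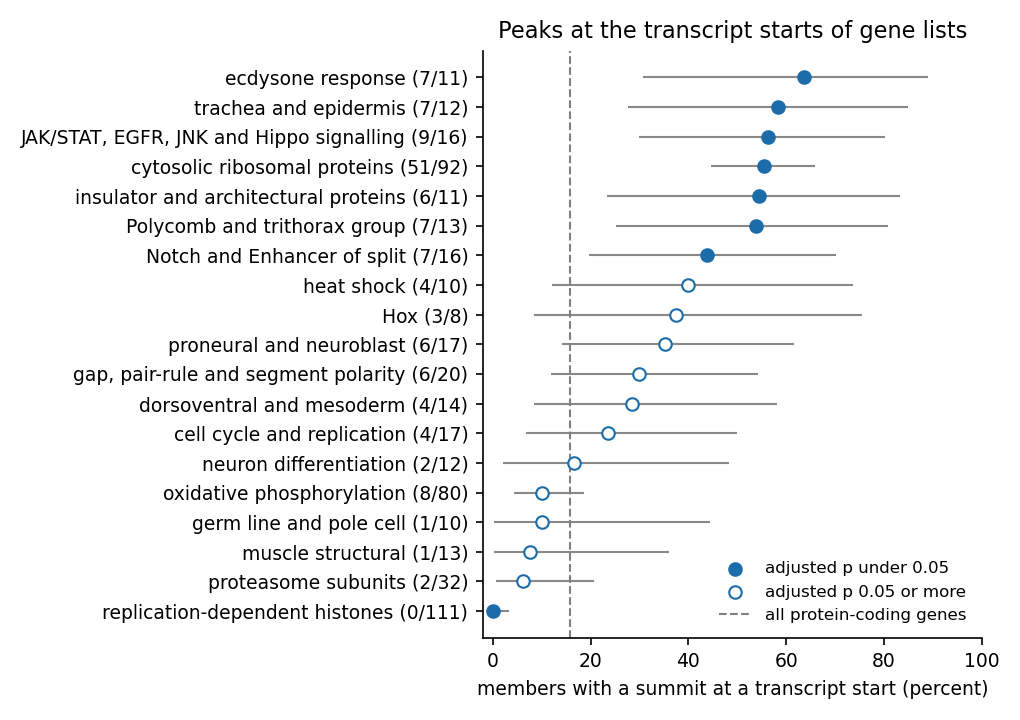
Percent of the measured members of each gene list (x axis) with a conservative summit within 500 bp of a transcript start, with exact 95% binomial intervals. Filled points passed the adjusted threshold, and the dashed line marks the 15.9% of all protein-coding genes.

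Gene types differed in how often a start had a peak. Protein-coding genes had a summit within 500 bp of a start in 15.9% of cases, against 7.50% of all other genes (odds ratio 2.32, 95% interval 2.06 to 2.63, adjusted Fisher p = 7.16e-48). Long non-coding RNA genes were below the other genes, with 220 of 2448 (0.576, adjusted Fisher p = 9.89e-15), as were microRNA genes with 13 of 260 (0.323, adjusted p = 9.71e-06). The same held for tRNA genes with 23 of 290 (0.530, adjusted Fisher p = 0.00301) and snoRNA genes with 24 of 269 (0.604, adjusted p = 0.0195). Small nuclear RNA genes had 8 of 32 (2.07, adjusted Fisher p = 0.0748). They passed in replicate 1 alone (2.53, adjusted Fisher p = 0.0272) and with a distance of 250 bp (2.44, adjusted p = 0.0414). The tRNA genes lost their call in the pooled list (0.776, adjusted Fisher p = 0.184) and snoRNA genes with gene 5′ ends only (0.711, adjusted p = 0.130). Many snoRNA genes lie inside host genes, and with a distance of 1000 bp their odds ratio was 1.31 (adjusted Fisher p = 0.0796).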

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

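The bounds of the 3 tests below were written before their results were seen, after the calls themselves had been noticed. Some calls of high signal were not part of the comparisons. The conservative ranked list held 178 calls that passed the IDR threshold and yet were absent from the thresholded list. Of these, 176 lay on the major arms in 63 places, joined where calls were within 10 kb, and 119 lay on 3R (67.6%, against 21.9% of the retained peaks). Their median signal was 125.6, against 103.9 for the retained peaks. Places singled out after their values were seen included tara with 15 calls, InR, the insulin receptor gene, with 10, cwo, a clock gene, with 7, and Sin3A, a corepressor gene, with 7. The strongest calls near Alh (1450), puc (1140), Rh5 (1132) and spen (1113) would have ranked 22, 44, 46 and 49 among the retained peaks.

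Exclusion of a fixed set of regions from every thresholded list may account for these calls. Taking each replicate in turn and summing both directions, which counts shared places more than once, 208 such calls met a call past the threshold in the other replicate. All 208 (100%) met one that the other thresholded list lacked too. Repeat sequence argues poorly as the reason, since the soft-masked share of sequence at these summits was 0.949 times that at retained summits (27.7% against 29.2%). They resembled ordinary sites, with a promoter share 3.55 percentage points above that of retained peaks (44.9% against 41.3%), and 44.3% held CAACAAC against 45.1%. What defined the regions is not given in the sources used here, and no biological explanation was tested. The list of signalling genes counts puc as without a peak, although absent calls lay nearest to it. The same held for trx and osa of the Polycomb and trithorax list and for the histone gene His2B:CG33868. These members were picked after the data were seen. Distances of the absent calls to a start are not given here, so whether each member would count is open.

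The conservative list also held 5 peaks on sequences outside the major arms. They lay on 3 unplaced sequences assigned to the X, with signals from 2.35 to 87.7.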

How the results depend on the processing

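Of 771 single values recomputed under the alternatives, 696 kept their side of the threshold, 41 lost a call, 27 gained one and 7 turned. Values that passed in neither setting are among the 696 even where their odds ratio crossed 1. The promoter odds ratio stayed between 2.96 and 4.51 over 12 alternatives, and that of CAACAAC between 11.4 and 27.8 over 10. The planned IDR of at most 0.01 equalled the deposited threshold, so it could move nothing. Its values are nevertheless counted among the 771 and the 696, and among the 12 alternatives of the promoter odds ratio. At an IDR of at most 0.001, chosen after seeing the data, the lists held 2835 (replicate 1), 2294 (replicate 2), 3452 (pooled) and 2992 (conservative) peaks, 3 arms passed in place of 5, and the odds ratio of the X was 1.03. Shared percentages for replicate 1 and replicate 2 were 67.0 and 80.6 with an overlap of 1 bp, 61.1 and 75.0 with summits at most 100 bp apart, and 62.3 and 62.9 with equal numbers of peaks. With each replicate list alone, 2 to 3 arms passed, the X had odds ratios of 1.07 to 1.12, 332 to 548 words were more frequent at summits, and 0 to 2 peaks lay at CG4360. The pooled list had 2 peaks at CG4360. Against random positions the X had an odds ratio of 1.10. Using gene 5′ ends left 4 gene lists and turned introns (1.06). Windows of 100 bp to each side gave 991 words and turned Ohler motif 6 (2.01), and a distance of 1000 bp turned snoRNA genes (1.31). Each replicate list held fewer peaks than the conservative list. Whether this or anything else caused the changes was not tested. Read depth is unknown, so its effect on the lists could not be measured.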

Other observations

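The bounds of the tests of explanations in this part were written before their results were seen, while all other breakdowns here were chosen after seeing the data. The genes with the most summits were picked by count, which favours long genes. Neighbouring summits that can match the same replicate peak were counted separately. The transcription factor gene sbb held 25 summits in 79.1 kb, mam held 21 in 69.2 kb and jing held 19 in 119.8 kb. Tlk, a kinase gene, and the genes bun, hth, kirre, rdx and ush each held 17. Their density ranged from 0.431 summits per 10 kb at kirre to 2.64 at ush, against 0.414 over the major arms. CHES-1-like held 16 summits in 27.0 kb, or 5.92 per 10 kb, the highest density among the 12 genes with the most summits.

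Across the genome, CAA runs carried peaks at high rates. Runs of at least 3 units of the same repeat within 100 bp of each other were joined and counted as 1. A joined run took the length and position of its longest member. Of 3478 such runs with a length of at least 12 bases, 1195 had a conservative summit within 100 bp (34.4%, exact 95% interval 32.8 to 36.0). At promoters 58.4% of runs had a summit (54.2 to 62.5), in 5′ UTRs 48.6%, in introns 32.9% (30.3 to 35.6), in coding sequence 29.6%, in intergenic sequence 23.6% and in 3′ UTRs 18.5%. By Cochran-Mantel-Haenszel chi-square tests over 4 strata of run length, runs of at least 3 units at promoters were occupied more often than intronic ones (common odds ratio 3.51, 95% interval 3.15 to 3.91). By the same chi-square test, runs in coding sequence (0.693, adjusted p = 2.81e-05) and in intergenic sequence (0.596, adjusted p = 3.16e-15) were occupied less often than intronic ones.

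Peaks with and without the repeat lay in different places. Of peaks with CAACAAC, 33.9% were at promoters, against 47.5% of those without it (odds ratio 0.566, 95% interval 0.508 to 0.631). The ribosomal protein genes stood apart among promoter peaks. Only 2 of their 57 promoter peaks had the word (3.51%), against 37.8% of the 2296 other promoter peaks (odds ratio 0.0598, adjusted Fisher p = 3.60e-08 over 18 lists). None of the other 17 lists differed past the threshold, the proneural list coming nearest with 8 of 12 (adjusted Fisher p = 0.354). At toy no copy of CAACAAC lay within 1000 bp of the summit, and at Ugalt the nearest was 77 bp away. The scyl summit had a run of 7 CAA units and the mam summit a run of 6.

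A candidate explanation of the CAA repeat at summits is binding of the tagged protein at the repeat. The share of joined CAA runs with a summit rose from 10.1% at 3 units to 30.2% at 4 and 38.7% at 5. It was 44.9% at 6 or more, a ratio of 4.44 between the longest and shortest. Because a joined run took the length of its longest member, length was not separated from the number of copies nearby. A general tendency of 3-base repeats to gather peaks was argued against, and repeats of other unit lengths were not tested in this way. Runs of the 9 other 3-base units were joined in the same way, leaving out those within 200 bp of a CAA run. They had a median of 0.672%, which is 1.955% of the CAA value. The highest share was 1.54% for AAG, with 1.21% for CAG and 0.929% at random positions. Promoter sequence alone was also argued against, since the odds ratio of CAACAAC at peaks over 500 bp from any transcript start was 18.96 (95% interval 16.7 to 21.5). Signal at the repeat in flies without the tagged protein stays open, because the control experiment was not analysed here. Recruitment through another protein that binds the repeat also stays open, since nothing measured here separates it from direct binding.

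Some peaks passed the threshold with a low signal value of their own. There were 229 under a value of 30 (4.02%), with a median of 9.07, while their matching peaks in the replicates had medians of 40.7 and 41.0. They may be the flanks of stronger peaks, since 182 of 229 (79.5%) lay within 500 bp of a call at least 5 times stronger. Among the other peaks the share was 0.421%, but the bar scales with a peak's own signal, so weak peaks meet it more easily. The split on signal thus sets much of that contrast, and no conclusion is drawn from it. The share of 79.5% was just under the 80% set beforehand, so the explanation stays open. CAACAAC was present at 6.11% of them. Without them the promoter odds ratio was 3.59.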
